A study of Mus musculus with 9 samples.

How the data were processed

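Hearts of 15-week-old male FVB mice were measured on an Affymetrix mouse genome array, with 3 wild-type (WT) mice, 3 mice with a kinase-deficient phosphofructokinase 2 in the heart (GlycoLo) and 3 with a phosphatase-deficient one (GlycoHi). Hearts were snap-frozen, RNA was taken up in Trizol and biotin-labelled cRNA was hybridised, per the labels' protocols. The authors deposited log2 values, summarised by the robust multiarray average method (RMA) per the file headers; the background and scaling settings of that step are not given in the sources used here. A second deposited table holds the same log2 values with gene symbols and the authors' own fold changes, p-values and adjusted p-values. Its 9 value columns differed from the first table by at most 8.9e-16, so it gave no separate alternative.

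The value table holds 45101 probe sets. The 64 control probe sets were left out of the tests, which ran on 45037. The authors' table names 1 gene symbol for 19760 of these (43.9%), several symbols for 876 and a spreadsheet date for 24, and the remaining 24377 are unnamed here. The listed probe sets varied more over the 9 arrays (median SD 0.136) than the unlisted ones (0.108). Each symbol stands for 1 listed probe set, so other probe sets of the same gene could not be compared by name, and gene lists used that probe set in place of the planned one with the highest mean. Of the 19760 symbols, 17779 were current in the RefSeq gene table of assembly GRCm38.p6, 645 were synonyms and 1336 did not match; symbols are printed as the authors' table gives them. No coordinates are printed, since the sources used here name no build for the array.

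Genotypes were compared with limma 3.58.1 in R 4.3.3. One linear model with the 3 genotypes was fitted to all 9 arrays, followed by empirical Bayes moderation (6 residual and 4.66 prior degrees of freedom). The 3 pairwise contrasts and the F-test over genotypes were adjusted by Benjamini-Hochberg over all probe sets tested, and a probe set was called at an adjusted p under 0.05. Errors given after a log2 difference are the model's SE; errors after a level are the SD over n = 3 mice. With 3 mice against 3, an exact permutation test of 1 gene cannot go below p = 0.1.

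Before the data were examined, 30 pathway lists and 14 cell type lists were fixed. Each was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 44 lists within a comparison, and again with an estimated correlation and with fry. Members were counted as risen or fallen over all probe sets tested and, where so stated, adjusted over the list alone. Genes were named by a rule fixed at the same time: up to 8 largest rises and 8 largest falls per comparison among called probe sets with 1 symbol whose groups did not overlap, the 4 Pfkfb genes, up to 4 members with the smallest p of each list that was called or had a called member, and up to 5 genes per combination of directions among those called in both lines. Levels near the top of the scale can be compressed by scanner saturation and those near the bottom are close to background, so folds at either end carry that limit; the number of arrays sets the precision.

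The alternatives tried were the replicate number as a block, only the 6 arrays compared, leaving out dim probe sets, a common median, cyclic loess, an offset of 50, a trended and robust variance, array weights, an adjusted p under 0.1, a 1.5-fold minimum and each array left out in turn. The labels' replicate numbers are shared by the 3 groups but no label says that a number marks a litter, batch or day. In the data only the replicate 1 arrays correlated best with their own number in both other groups. The block is reported only among the alternatives. Because both lines share the WT arrays, unchanged groups were simulated against shared controls. Noise in this simulation and in the one that follows was drawn independently for each probe set. The steps were tested on simulated data with the array's own means and spreads, 200 probe sets being changed in GlycoHi against WT over 45037 probe sets: 72.0% of 50 changes of 0.5 on the log2 scale were recovered, and all 50 at each of 1, 2 and 4. The genes of the TCA cycle list were lowered by 0.3 as well. Of all calls made there, 200 in number and some of them of that list, 8 were false. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.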

Results

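Gene expression was measured in whole hearts of adult male mice of 3 genotypes, with 3 mice and 1 array per mouse in each. Phosphofructokinase 2 sets the level of fructose 2,6-bisphosphate, an activator of glycolysis, through a kinase and a phosphatase activity in 1 protein. GlycoLo hearts expressed a kinase-deficient form and GlycoHi hearts a phosphatase-deficient form, and the comparisons ask how the cardiac transcriptome differs when this control point is set low or high. The median log2 value of an array lay between 4.76 and 4.80, and the correlation between any 2 arrays, across probe sets, was 0.994 to 0.997. The first principal component (29.3% of the variance) set the GlycoHi arrays apart and the second (16.1%) the GlycoLo arrays. The difference between the 3′ and 5′ probe sets of actin, a sign of RNA integrity, was 0.95 ± 0.04 in WT, 0.90 ± 0.01 in GlycoLo and 0.90 ± 0.08 in GlycoHi (SD, n = 3).

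Pfkfb1, the gene of the liver isoform of phosphofructokinase 2, was expressed at 7.89 ± 0.13 in WT hearts and at 14.36 ± 0.02 in GlycoLo and 14.42 ± 0.01 in GlycoHi (log2, SD, n = 3). It rose by 6.47 ± 0.07 in GlycoLo (adjusted p = 4.79e-12) and by 6.53 ± 0.07 in GlycoHi (adjusted p = 4.38e-12). Its probe set ranked 2 from the top of the array on every GlycoLo array and 1 on every GlycoHi array, so the fold may be compressed at the top of the scale. Its difference between the lines was not called (0.06 ± 0.07, adjusted p = 0.810). Pfkfb3, an inducible isoform, rose in GlycoHi by 0.57 ± 0.08 (adjusted p = 0.00536); its difference in GlycoLo was 0.50 ± 0.08 and was not called (adjusted p = 0.0733). Pfkfb2, the cardiac isoform, differed by 0.32 ± 0.16 in GlycoLo and 0.21 ± 0.16 in GlycoHi, and Pfkfb4 by -0.01 ± 0.12 and 0.04 ± 0.12, none of them called. The list of these 4 genes, carried by Pfkfb1, was called up in GlycoLo by camera (adjusted p = 2.74e-07, and adjusted p = 0.0436 with an estimated correlation). In GlycoHi it had an adjusted p = 1.69e-05, and an adjusted p = 0.0769 with an estimated correlation. Both lines express an altered phosphofructokinase 2, so the rise of Pfkfb1 may be the transgene itself. The call of this list is therefore no test of a response.

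The largest called falls in GlycoLo against WT, among genes with 1 symbol, were those of Fbp2, Bdh1 and Fah, and the largest rises those of Pfkfb1 and Myh7. Fbp2, the muscle fructose-1,6-bisphosphatase, fell by 1.44 ± 0.08 on the log2 scale (from 7.41 ± 0.06 to 5.97 ± 0.16, SD, n = 3; adjusted p = 9.01e-05). Bdh1, the mitochondrial enzyme that interconverts the ketone bodies, fell by 1.36 ± 0.10 (adjusted p = 0.000238). Acot1, a cytosolic acyl-CoA thioesterase, fell by 1.14 ± 0.11 (adjusted p = 0.00210). Fah, of tyrosine breakdown, fell by 1.21 ± 0.11, and Abat, the GABA transaminase, by 1.10 ± 0.14. Sox6, a transcription factor, fell by 0.97 ± 0.07, Cmtm6 by 0.91 ± 0.08 and Hamp, which encodes the iron hormone hepcidin, by 0.90 ± 0.12. Besides Pfkfb1, the rises were led by Myh7, the slow myosin heavy chain, at 2.75 ± 0.24 (13.77 ± 0.05 against 11.02 ± 0.65 in WT; adjusted p = 0.00155). Next came Bex1 at 1.38 ± 0.17 and Fam101a at 1.34 ± 0.09. Casq1, a calcium store protein of skeletal muscle, rose by 0.73 ± 0.10, Cdc34 by 0.58 ± 0.09 and Pdlim7 by 0.54 ± 0.07. The difference in Myh7 exceeded the spread of the WT hearts, the widest of the 3 groups for this gene.

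Several lists of lipid genes were called down in GlycoLo by camera. Of 24 PPAR alpha targets, genes switched on by the fatty acid receptor, 3 fell (Acot1, Cidea by 0.74 ± 0.10 and Ces1d by 0.70 ± 0.10), 0 rose and 21 were not called. When adjusted over the list alone, 15 fell. This list was called down by camera (adjusted p = 4.65e-18) and remained so with an estimated correlation (adjusted p = 0.0436). Of 25 genes of fatty acid oxidation, Decr1 fell by 0.58 ± 0.07 and 24 were not called, against 12 that fell adjusted over the list alone, such as Cpt2 at -0.39 ± 0.07 and Acot2 at -0.83 ± 0.15. That call had an adjusted p = 1.32e-14 and was lost with an estimated correlation (adjusted p = 0.291). Bdh1 was the 1 called member of the 7 ketone body genes (camera adjusted p = 0.00250, and adjusted p = 0.417 with an estimated correlation), where Oxct1, which activates acetoacetate, stood at -0.34 ± 0.06. Ivd, of leucine breakdown, fell by 0.53 ± 0.06 and was the 1 called member of 20 genes of branched-chain amino acid catabolism. Adjusted over the list alone, 8 fell. By camera the list had an adjusted p = 4.78e-06, or an adjusted p = 0.307 with an estimated correlation. The lipid storage list held 1 fall, Cidea, and 25 genes not called. The list reached an adjusted p = 0.00907 by camera and an adjusted p = 0.307 with an estimated correlation. Markers of white adipocytes were called down in the same comparison (median -0.22 over 11 genes, none called; adjusted p = 0.0317, and adjusted p = 0.425 with an estimated correlation), and the level of Adipoq, an adipocyte hormone, was 5.75 ± 0.85 against 6.53 ± 1.11 in WT, where it reached 7.78 in WT replicate 3. In the ketone body, lipid storage and white adipocyte lists 4, 5 and 2 genes fell adjusted over the list alone, and 1 ketone body gene rose. With fry the PPAR alpha, fatty acid oxidation and ketone body lists were called down (adjusted p = 0.00420, 0.0151 and 0.0353). The branched-chain amino acid, lipid storage and white adipocyte lists were not called by fry (adjusted p = 0.0531, 0.133 and 0.278). Decr1 and Ivd lost their calls without any single WT or GlycoLo array (adjusted p up to 0.106), and Ces1d without any of these or GlycoHi replicate 2 (up to 0.179). Cidea lost its call without WT replicate 1 or 3 or any single GlycoLo array (up to 0.114). The camera call of the lipid storage list ended without WT replicate 3 or GlycoLo replicate 2 (up to 0.155), and that of white adipocytes without WT replicate 3 or GlycoLo replicate 1 or 2 (up to 0.389).

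Glycolysis and mitochondrial respiration held no called gene in GlycoLo: 0 of 21 glycolytic genes, 0 of 19 genes of the TCA cycle and 0 of 44 genes of oxidative phosphorylation were called, with medians of 0.02, -0.02 and 0.03. Junb, an immediate early transcription factor, fell by 0.57 ± 0.07, the 1 called member of 20 immediate early genes, of which 7 fell adjusted over the list alone. For this list, camera found an adjusted p = 4.44e-07, and an adjusted p = 0.307 with an estimated correlation. The heat shock list was called down with none of its 16 genes called, Hspa1b standing at -2.39 ± 0.61 and Hspa8 at -1.23 ± 0.22. Camera gave this list an adjusted p = 1.71e-06, and an adjusted p = 0.425 with an estimated correlation. Among 19 clock genes none was called, yet adjusted over the list alone 5 fell, among them Ciart at -1.34 ± 0.21, and 4 rose, among them Arntl at 0.65 ± 0.19 (camera down, adjusted p = 0.0197, and adjusted p = 0.425 with an estimated correlation). Usp18 fell by 0.47 ± 0.07 among 22 interferon response genes. By camera the list had an adjusted p = 0.00791, or an adjusted p = 0.465 with an estimated correlation. Shmt1 fell by 0.67 ± 0.09 among 17 genes of serine, glycine and one-carbon metabolism, and Kcnv2 by 0.66 ± 0.09 among 31 genes of calcium handling and ion channels. Other lists called down, with no called member, were erythroid markers (median -0.39 over 8 genes), macrophage (-0.18), endothelial (-0.12), epicardial (-0.10) and extracellular matrix genes (-0.10), whose adjusted p with an estimated correlation lay between 0.307 and 0.440. Junb lost its call without any single WT or GlycoLo array (adjusted p up to 0.106), and Usp18 without any single array (up to 0.143). Shmt1 lost its call without WT replicate 1 or 2, any single GlycoLo array or GlycoHi replicate 1 (up to 0.118), and Kcnv2 without any single WT array, GlycoLo replicate 1 or 2 or GlycoHi replicate 1 (up to 0.120). Camera no longer called the clock list without WT replicate 1 or GlycoLo replicate 2 (up to 0.246), or the interferon list without GlycoLo replicate 1 (0.457). The endothelial list was lost without WT replicate 1 or 2 or GlycoLo replicate 1 or 2 (up to 0.283), the epicardial list without WT or GlycoLo replicate 2 (up to 0.278) and the macrophage list without GlycoLo replicate 2 (0.0505).

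In all, 38 probe sets were called between GlycoLo and WT, 7 higher and 31 lower, and 28 of them carried 1 gene symbol. An unadjusted p under 0.05 was reached by 4270 probe sets, where chance gives 2251.85. All 38 had non-overlapping groups, which a call with 3 mice per group nearly requires. Among all probe sets the share was 13.2%, where chance gives 10%. The count fell to 13 without WT replicate 1, to 14 without WT replicate 2 or 3, to 13 without GlycoLo replicate 2 and to 15 without GlycoLo replicate 1 or 3. It rose to 256 with a trended and robust variance. The calls of Casq1, Cdc34 and Pdlim7 were lost on omission of any single WT or GlycoLo array (highest adjusted p over the alternatives 0.150, 0.162 and 0.133), and that of Bex1 without any single WT array or GlycoLo replicate 2 (0.0977). Hamp lost its call without any single WT array or GlycoLo replicate 2 or 3 (0.119), and Abat without WT replicate 1 or 3 or any single GlycoLo array (0.114). Without single GlycoHi arrays, which enter the variance, Cdc34 lost its call each time, Casq1 without replicate 2 or 3, and Pdlim7 and Abat without replicate 3.

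**Figure D1:**
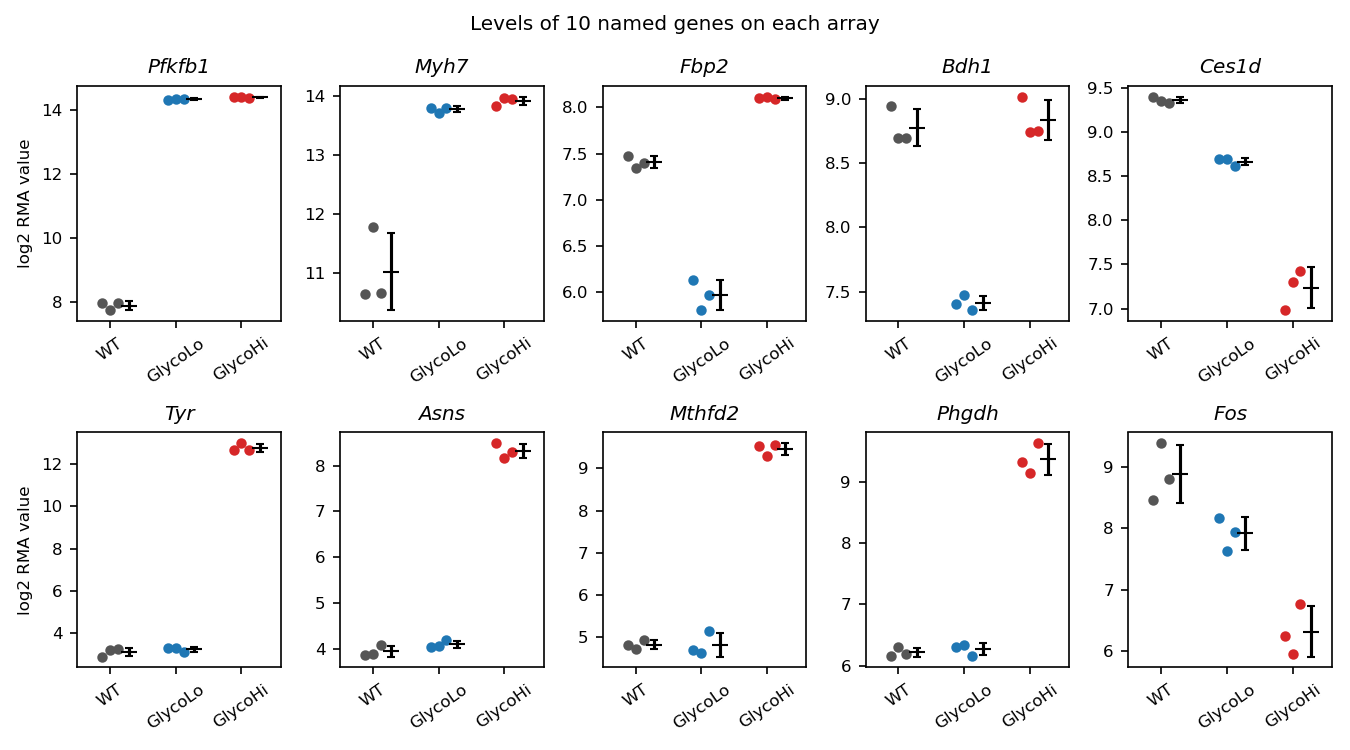
Log2 RMA value (vertical axis) of 10 named genes on each array, by genotype (horizontal axis); dots are mice, bars beside them the mean ± SD of 3, and each panel has its own scale that does not start at 0. Pfkfb1 and Myh7 are high in both lines, Fbp2 lies at 5.97 in GlycoLo and 8.10 in GlycoHi with WT between them, and Tyr, Asns, Mthfd2 and Phgdh stand apart in GlycoHi.

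Among genes with 1 symbol, the largest called rises in GlycoHi against WT were those of Tyr, Pfkfb1, Mthfd2 and Asns, and the largest falls those of Fos and Ces1d. Mthfd2, the mitochondrial enzyme of the folate cycle, rose by 4.62 ± 0.13 (from 4.83 ± 0.10 to 9.45 ± 0.14, SD, n = 3; adjusted p = 1.93e-08). Asns, asparagine synthetase, rose by 4.39 ± 0.09 (adjusted p = 1.66e-09) and Phgdh, the first enzyme of serine synthesis, by 3.15 ± 0.11 (adjusted p = 1.40e-07). Tyr, the tyrosinase of melanin synthesis, rose from 3.10 ± 0.20, in the 18.2th percentile of the WT array, to 12.78 ± 0.18, by 9.68 ± 0.12 (adjusted p = 6.35e-12). Bex1 rose by 3.09 ± 0.17, Myh7 by 2.89 ± 0.24 and Tchhl1 by 2.27 ± 0.19. The falls were led by Fos, an immediate early transcription factor, which fell by 2.56 ± 0.25 (from 8.88 ± 0.47 to 6.32 ± 0.41; adjusted p = 0.000368). Ces1d, a carboxylesterase that acts on lipid esters, fell by 2.12 ± 0.10 (adjusted p = 1.74e-06).

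Of 17 genes of serine, glycine and one-carbon metabolism, 4 rose in GlycoHi (Mthfd2, Phgdh, Aldh1l2 by 1.67 ± 0.09 and Psat1 by 0.69 ± 0.11), 0 fell and 13 were not called. Adjusted over the list alone, 7 rose and 1 fell. The list was called up by camera (adjusted p = 3.50e-05), which was lost with an estimated correlation (adjusted p = 0.163). Of 23 genes of the unfolded protein and integrated stress response, 6 rose (Asns, Atf5 by 2.26 ± 0.07, Trib3 by 2.02 ± 0.16, Gdf15 by 1.91 ± 0.23, Chac1 by 1.26 ± 0.19 and Ddit3 by 0.59 ± 0.10) and 17 were not called. The remaining members leaned the other way, so that the list's median was -0.06 while its mean was 0.45. Camera called it up (adjusted p = 0.0440, and adjusted p = 0.493 with an estimated correlation); adjusted over the list alone 8 rose and 7 fell. The 22 genes of cell cycle and proliferation included 3 that rose, Ccnd2, a G1 cyclin, by 1.48 ± 0.16, Mcm2 by 0.79 ± 0.11 and the cell cycle inhibitor Cdkn1a by 0.70 ± 0.15. Cenpa fell by 0.66 ± 0.08 (camera up, adjusted p = 0.0216, and adjusted p = 0.163 with an estimated correlation). Cdkn1a lost its call without WT replicate 1 or 2, GlycoLo replicate 2 or 3 or GlycoHi replicate 1 or 2 (adjusted p up to 0.140). The camera call of the stress list ended without WT replicate 1 or 2, GlycoLo replicate 1 or 2 or GlycoHi replicate 1 (up to 0.172), and that of the cell cycle list without WT replicate 2 or GlycoHi replicate 3 (up to 0.0706).

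Of 20 immediate early genes 10 fell in GlycoHi, among them Fos, Fosl2 by 0.72 ± 0.07, Junb by 0.70 ± 0.07 and Nr4a1 by 0.91 ± 0.16, and 0 rose. Of these genes, adjusted over the list alone, 13 fell and 3 rose. The list reached an adjusted p = 1.35e-09 by camera and an adjusted p = 0.163 with an estimated correlation. Hspa8 fell by 1.10 ± 0.22 and was the 1 called member of 16 heat shock genes. For this list, camera found an adjusted p = 1.95e-05, and an adjusted p = 0.316 with an estimated correlation. Of 31 genes of calcium handling and ion channels, 3 fell, among them Kcnip2 and Kcnd2, subunits of the transient outward potassium channel, by 1.80 ± 0.28 and 0.48 ± 0.07. Slc8a1, the sodium-calcium exchanger, rose by 0.53 ± 0.10, and 27 were not called. Adjusted over the list alone, 15 fell and 1 rose. Camera gave this list an adjusted p = 1.73e-06, and an adjusted p = 0.0769 with an estimated correlation. In the sarcomere list Myh7 rose while Myh6, the fast myosin of the adult mouse ventricle, fell by 0.70 ± 0.10 and Tpm1 by 1.14 ± 0.19, and 21 of 24 were not called (camera adjusted p = 0.0968). The heat shock list held 8 falls adjusted over the list alone. Hspa8 lost its call without any single WT array or GlycoHi replicate 2 (adjusted p up to 0.103), and Slc8a1 without WT replicate 2 or 3 or GlycoHi replicate 1 or 2 (up to 0.101).

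The TCA cycle and oxidative phosphorylation lists were called down in GlycoHi by camera, though few of their genes were called. Of 19 TCA cycle genes, Sdhd fell by 0.37 ± 0.07, Dld by 0.39 ± 0.08 and Sucla2 by 0.27 ± 0.06, and 16 were not called. Adjusted over the list alone, 10 fell. By camera the list had an adjusted p = 1.69e-05, or an adjusted p = 0.203 with an estimated correlation. Cox7a1 fell by 0.34 ± 0.06 among 44 genes of oxidative phosphorylation. The list reached an adjusted p = 6.35e-05 by camera and an adjusted p = 0.332 with an estimated correlation. Of 20 genes of branched-chain amino acid catabolism 4 fell, among them Dbt by 0.63 ± 0.09, Ppm1k by 0.57 ± 0.09 and Ivd by 0.43 ± 0.06. For this list, camera found an adjusted p = 3.50e-05, and an adjusted p = 0.163 with an estimated correlation. Fatty acid oxidation held 0 called genes of 25 (median -0.06, camera adjusted p = 0.329). In glycogen metabolism Pygl, the liver glycogen phosphorylase, fell by 1.27 ± 0.11 and Ppp1r3b, a glycogen-targeting phosphatase subunit, by 0.82 ± 0.16, while Gyg, which primes glycogen synthesis, rose by 0.34 ± 0.06. Camera gave this list an adjusted p = 0.0440, and an adjusted p = 0.405 with an estimated correlation. Of 21 glycolytic genes Pgam1 rose by 0.49 ± 0.08 and 20 were not called (camera adjusted p = 0.776). Among PPAR alpha targets 3 of 24 fell, among them Ces1d and Retsat, by 0.63 ± 0.13. By camera the list had an adjusted p = 0.0227, or an adjusted p = 0.333 with an estimated correlation. White adipocyte markers moved in the same direction: 2 fell, among them Thrsp by 0.98 ± 0.10, 9 of 11 were not called, and Adipoq stood at 4.89 ± 0.63 against 6.53 ± 1.11 in WT. The list reached an adjusted p = 0.000110 by camera and an adjusted p = 0.163 with an estimated correlation. The counts adjusted over the list alone were 2 falls for oxidative phosphorylation, 6 for branched-chain amino acid catabolism, 5 falls and 1 rise for glycogen, 5 falls for PPAR alpha targets and 5 for white adipocyte markers. Sucla2 lost its call without any single array (adjusted p up to 0.142), Dld without any single WT array or GlycoHi replicate 2 or 3 (up to 0.0925) and Sdhd without WT replicate 1 or 3 or GlycoHi replicate 2 or 3 (up to 0.0857). Cox7a1 lost its call without WT replicate 1 or 2 or GlycoHi replicate 2 (up to 0.0676), and Ppp1r3b without WT replicate 2 or any single GlycoHi array (up to 0.0910). Gyg lost its call without WT replicate 2 or 3 or GlycoHi replicate 1 or 2 (up to 0.0698), Pgam1 without GlycoHi replicate 2 (0.0524) and Retsat without any single WT array, GlycoLo replicate 2 or GlycoHi replicate 2 or 3 (up to 0.113). Camera no longer called the glycogen list without WT replicate 1 or GlycoHi replicate 3 (up to 0.340), or the PPAR alpha list without WT replicate 1 or GlycoHi replicate 2 (up to 0.127).

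Markers of several cell types were called down in GlycoHi beside the channel and mitochondrial lists, with at most 1 member called in each. They were those of cardiomyocytes (median -0.04 over 12 genes, camera adjusted p = 0.0130), atrial and conduction myocardium (-0.28, 0.00166), endothelium (-0.12, 0.00608), smooth muscle and pericytes (-0.21, 0.00937), brown adipocytes (-0.16, 0.00682), neutrophils (-0.11, 0.0216), erythroid cells (-0.35, 0.0104) and epicardium (-0.26, 0.0130). With an estimated correlation their adjusted p lay between 0.163 and 0.332. The endothelial and erythroid calls ended without WT replicate 1 (0.0708 each), the epicardial call without WT replicate 2 or GlycoHi replicate 1 (up to 0.164) and the neutrophil call without WT replicate 2 (0.0791). Camera also called down the lists of lipid storage (2 of 26 fell, 1 rose), pyruvate entry (1 of 15 fell), extracellular matrix (1 of 34 fell, 1 rose), glucose response (1 of 13 fell) and exercise-associated growth (2 of 18 fell, 1 rose), the other members not being called (camera adjusted p 0.00997 to 0.0434, and 0.163 to 0.277 with an estimated correlation). These calls ended without WT replicate 3 for lipid storage, WT replicate 1 for pyruvate entry, WT replicate 2 for extracellular matrix and WT replicate 1 or GlycoHi replicate 2 for glucose response. That of exercise-associated growth ended without WT replicate 1 or 2, GlycoLo replicate 2 or GlycoHi replicate 2 or 3 (adjusted p over these 5 lists up to 0.117).

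Between GlycoHi and WT, 938 probe sets were called, 487 higher and 451 lower, 616 of them with 1 symbol. A change of at least 2-fold was shown by 59 that rose and 22 that fell, and the median size of a called change was 0.48 on the log2 scale. All 938 had non-overlapping groups, which a call with 3 mice per group nearly requires. Among all probe sets the share was 18.2%. The count fell to 429 without WT replicate 2, 487 without WT replicate 3, 502, 528 and 569 without GlycoHi replicates 2, 3 and 1, and was 769 or fewer without any other array. With an estimated correlation, none of the 26 lists that camera called remained. Fry called 20 lists in this comparison. Frem2, which fell by 1.51 ± 0.11, and Cmtm6, by 1.25 ± 0.08, kept their calls in each alternative.

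**Figure D2:**
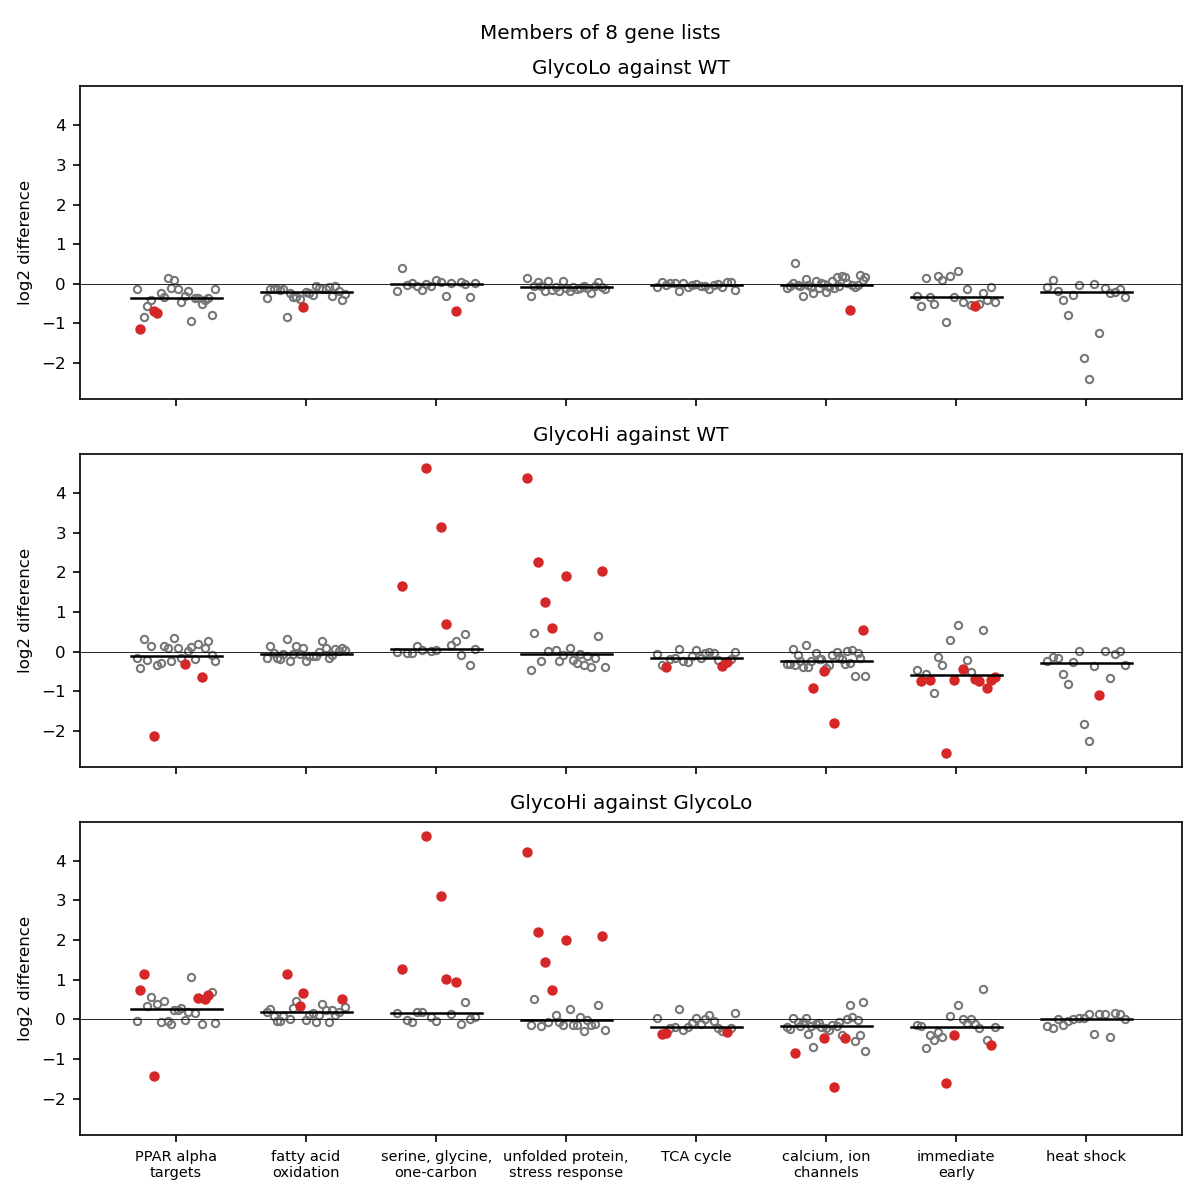
Log2 difference (vertical axis) of each member of 8 gene lists (horizontal axis) in the 3 comparisons; each point is 1 gene, filled where its adjusted p over all probe sets is under 0.05, and lines are list medians. The serine, glycine and one-carbon list and the stress response list hold high points in GlycoHi, up to Mthfd2 at 4.62 against WT, beside medians of 0.07 and -0.06.

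The direct comparison of the lines set Tyr at 9.56 ± 0.12 higher in GlycoHi than in GlycoLo (adjusted p = 1.45e-11). Mthfd2 stood at 4.63 ± 0.13, Asns at 4.23 ± 0.09, Phgdh at 3.10 ± 0.11, Tchhl1 at 2.31 ± 0.19, Atf5 at 2.20 ± 0.07 and Trib3 at 2.10 ± 0.16. Fbp2 was 2.13 ± 0.08 higher (8.10 ± 0.01 against 5.97 ± 0.16, SD, n = 3; adjusted p = 3.36e-07), and Bdh1 1.42 ± 0.10 higher (adjusted p = 3.80e-05). Lower in GlycoHi were Aqp4, a water channel, which fell by 1.78 ± 0.21, and Kcnip2, by 1.70 ± 0.28. Fos fell by 1.59 ± 0.25, Ces1d by 1.43 ± 0.10, Frem2 by 1.33 ± 0.11, Tnnt1, the slow skeletal troponin T, by 1.31 ± 0.10, Ddah1 by 1.13 ± 0.08 and Ppp1r3b by 1.12 ± 0.16. For Kcnip2 the GlycoHi hearts were spread widely (5.56 ± 0.75), and its call between the lines was lost without GlycoLo replicate 1 or 3 or GlycoHi replicate 3 (highest adjusted p over the alternatives 0.0682).

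The fatty acid oxidation and PPAR alpha lists were called up between GlycoHi and GlycoLo by camera. Of 25 genes of fatty acid oxidation 4 rose, Acot2 by 1.14 ± 0.15, Decr1 by 0.67 ± 0.07, Slc25a20, the carnitine-acylcarnitine carrier, by 0.51 ± 0.08 and Cpt2 by 0.33 ± 0.07, and 21 were not called. Adjusted over the list alone, 10 rose. For this list, camera found an adjusted p = 7.30e-07, and an adjusted p = 0.395 with an estimated correlation. Of 24 PPAR alpha targets 5 rose and Ces1d fell (camera up, adjusted p = 1.11e-05, and adjusted p = 0.281 with an estimated correlation). Ketone body metabolism held 2 rises, Bdh1 and Slc16a7 by 0.43 ± 0.09. Camera gave this list an adjusted p = 0.0157, and an adjusted p = 0.395 with an estimated correlation. In the opposite direction, 3 of 19 TCA cycle genes fell, Cs, citrate synthase, by 0.38 ± 0.08, Dld by 0.35 ± 0.08 and Sucla2 by 0.31 ± 0.06 (camera adjusted p = 0.00129, and adjusted p = 0.395 with an estimated correlation), and 2 of 44 genes of oxidative phosphorylation fell, Cox7a1 by 0.35 ± 0.06 and Ndufa10 by 0.30 ± 0.06. By camera the list had an adjusted p = 1.82e-06, or an adjusted p = 0.395 with an estimated correlation. Among calcium and channel genes 4 of 31 fell, Kcnip2, Cacna1g by 0.85 ± 0.10, Kcnd2 by 0.48 ± 0.07 and Kcnj5 by 0.48 ± 0.09. The list reached an adjusted p = 5.88e-06 by camera and an adjusted p = 0.0649 with an estimated correlation. Markers of atrial and conduction myocardium were called down with it (median -0.26 over 10 genes, none called, 3 falls adjusted over the list alone; camera adjusted p = 0.00134, and adjusted p = 0.395 with an estimated correlation). Cited4, listed among genes of exercise-associated cardiac growth, fell by 1.08 ± 0.15, and Tnni3k by 0.59 ± 0.10, with 16 of 18 not called. For this list, camera found an adjusted p = 0.00525, and an adjusted p = 0.198 with an estimated correlation. The counts adjusted over the list alone were 10 rises and 1 fall for PPAR alpha targets, 2 rises for ketone bodies, 9 falls and 1 rise for the TCA cycle, 12 falls and 2 rises for calcium and channels, and 4 falls for exercise-associated genes. Ndufa10 lost its call without any single array (adjusted p up to 0.117), Cs without any but GlycoHi replicate 1 (up to 0.131), Dld without any but GlycoLo replicate 3 (up to 0.168) and Cpt2 and Slc16a7 without any but WT replicate 1 (up to 0.139 and 0.157). Sucla2 lost its call without any single GlycoLo or GlycoHi array (up to 0.0912), and Cox7a1 without GlycoLo replicate 3 or GlycoHi replicate 2 or 3 (up to 0.0634). Kcnj5 lost its call without WT replicate 2, GlycoLo replicate 1 or 3 or GlycoHi replicate 1 or 3 (up to 0.122), and Tnni3k without any single GlycoLo array or GlycoHi replicate 2 or 3 (up to 0.0823). Camera no longer called the ketone body list without GlycoLo replicate 2 or GlycoHi replicate 1 (up to 0.0555).

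Serine, glycine and one-carbon genes rose in 5 of 17 cases between the lines, with Shmt1 at 0.95 ± 0.09 and Psat1 at 1.01 ± 0.11 beside Mthfd2, Phgdh and Aldh1l2. Camera gave this list an adjusted p = 4.45e-08, and an adjusted p = 0.0649 with an estimated correlation. The counts adjusted over the list alone were 6 rises here and 9 in the stress response list. That list held 6 rises of 23, its median at -0.01 and its mean at 0.53 (camera up, adjusted p = 0.000503, and adjusted p = 0.395 with an estimated correlation). Of 22 cell cycle genes 3 rose, among them Ccnd2 by 1.48 ± 0.16 and Mcm2 by 0.78 ± 0.11, and Cenpa fell by 0.74 ± 0.08 (camera up, adjusted p = 0.00401, and adjusted p = 0.189 with an estimated correlation). In the glycogen list 3 of 21 fell, among them Pygl by 0.91 ± 0.11 and Ppp1r3b (camera down, adjusted p = 0.0157, and adjusted p = 0.395 with an estimated correlation), a call that ended without GlycoHi replicate 3 (adjusted p 0.265). Of 20 immediate early genes 3 fell, among them Fos (camera down, adjusted p = 0.00158, and adjusted p = 0.395 with an estimated correlation). Ifit2 rose by 0.57 ± 0.07, the 1 called member of 22 interferon response genes (camera up, adjusted p = 0.0400, and adjusted p = 0.671 with an estimated correlation). That list was lost without GlycoLo replicate 1 or GlycoHi replicate 1 or 3 (adjusted p up to 0.833). The cell cycle list held 4 rises and 1 fall adjusted over the list alone, the glycogen list 5 falls, the immediate early list 5 falls and 1 rise and the interferon list 1 rise. Of 16 heat shock genes 0 were called, with a median of 0.01. In total 771 probe sets were called, 431 higher and 340 lower in GlycoHi. All of them had non-overlapping groups, which a call nearly requires, and among all probe sets the share was 16.8%. Single arrays moved this count to 375 without GlycoHi replicate 3, 381, 423 and 462 without GlycoLo replicates 3, 1 and 2, and 507 and 510 without GlycoHi replicates 2 and 1.

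The F-test over the 3 genotypes called 938 probe sets, and fewer without GlycoHi replicate 3 (483), 2 (543) or 1 (556), WT replicate 2 (545) or 3 (581) or GlycoLo replicate 3 (572). Called against WT in both lines were 19 probe sets. Of these, 5 were higher in both: Pfkfb1, whose rise may be the transgene itself, Myh7, Bex1, Fam101a and Cdc34. Another 13 were lower in both, among them Sox6, Cmtm6, Pcolce, Ces1d and Junb. The remaining 1, Fbp2, was lower in GlycoLo and higher in GlycoHi, by 0.69 ± 0.08 (adjusted p = 0.00186). Independent lists of these lengths would share 0.0757 probe sets higher in both, 0.310 lower in both and 0.335 lower in GlycoLo and higher in GlycoHi. Simulated unchanged groups against shared controls shared 0 calls, but groups without any change give almost no calls to share, so this could hardly come out otherwise. Real changes in both lines beside shared WT arrays were not simulated. Across probe sets, which are not independent replicates, the changes of the lines correlated at r = 0.459, against 0.484 to 0.513 for simulated unchanged groups that share their controls. The covariance of the changes was 0.0116, or 0.0107 without Pfkfb1, against a simulated mean of 0.00474. The simulation drew each probe set independently with the model's moderated spread. It does not reproduce noise shared between probe sets, so these simulated values decide nothing about the real ones. With 3 WT arrays the controls could not be split, so part of the overlap may come from the shared WT hearts. The 18 probe sets that moved the same way in both lines were 7 without WT replicate 1, 2 or 3, and 10, 8 and 9 without GlycoLo replicates 1, 2 and 3. Cdc34 lost its call in GlycoHi without WT replicate 2 or 3 or GlycoHi replicate 1 or 3 (adjusted p up to 0.0791). Bex1 rose further in GlycoHi than in GlycoLo (difference 1.71 ± 0.17, adjusted p = 0.000491) and Ces1d fell further, while Myh7 (0.14 ± 0.24, adjusted p = 0.863), Sox6 and Pcolce were not called between the lines.

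**Figure D3:**
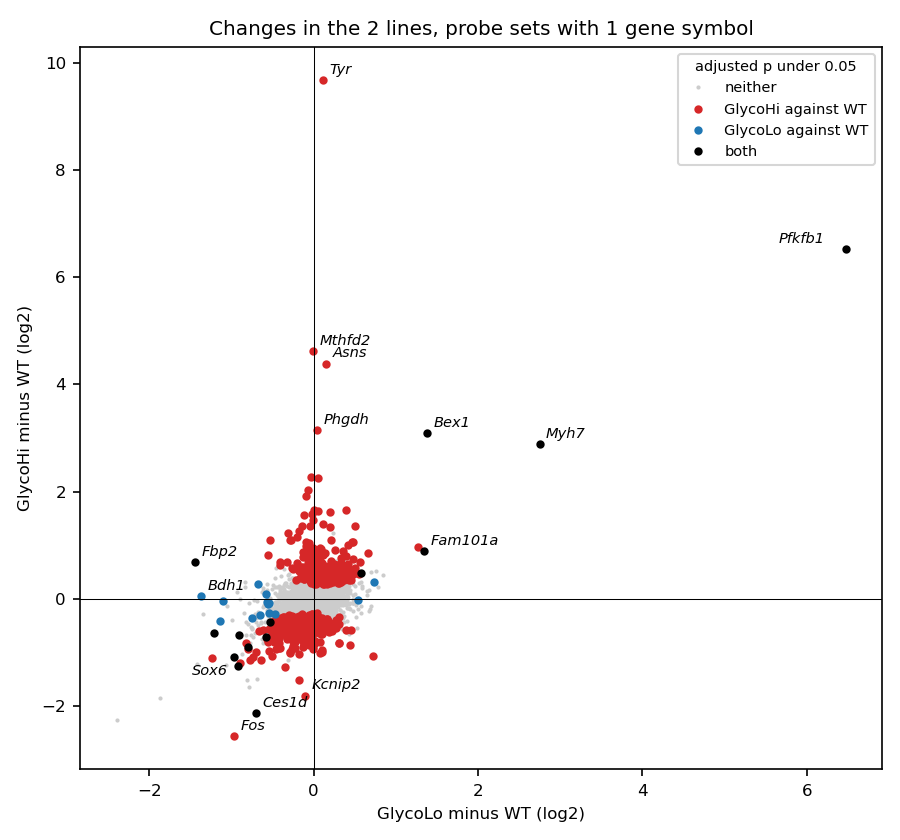
Change against WT in GlycoLo (horizontal axis) and in GlycoHi (vertical axis), log2, for the probe sets with 1 gene symbol; colours show in which line the adjusted p was under 0.05. Pfkfb1 and Myh7 lie far up in both directions, Tyr, Mthfd2, Asns and Phgdh lie along the GlycoHi axis, and Fbp2 is the called gene at upper left (-1.44 and 0.69).

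In the authors' deposited table, 29 probe sets had an adjusted p under 0.05 between GlycoLo and WT, 640 between GlycoHi and WT and 516 between GlycoHi and GlycoLo, out of 20662 listed. A limma fit of all 45101 probe sets, controls included, called the same 29, 640 and 516 among these, with p-values within 5.02e-06.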

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

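The tests of the additional Tyr copy, of both explanations for Myh7 and of the clock genes were chosen after the results were seen. Those of melanocyte markers and of the Tyr neighbours arose from the high Tyr level itself, and were written before they were run. Those of other splits of the arrays were written before.

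The effects of the 2 transgenes against WT differed by direct test at 771 probe sets. Fbp2 was called with opposite signs in the 2 lines, and its change in GlycoHi exceeded that in GlycoLo by 2.13 on the log2 scale.

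Tyr stood at 12.78 in GlycoHi and at 3.22 and 3.10 in GlycoLo and WT. Melanocytes in the GlycoHi samples would bring their other transcripts, but 10 further melanocyte markers had a median change of -0.10 (SD 0.28), with Tyrp1 at 2.99, Pmel at 4.51 and Dct at 5.61 in GlycoHi; 5 of the 10 lie above the median of all probe sets in WT hearts. Of the 10, Mlana was called lower in GlycoHi than in WT, by 0.82 (adjusted p = 0.0295, up to 0.103 without any single array but WT replicate 1 or GlycoLo replicate 1), and Dct higher in GlycoHi than in GlycoLo, by 0.57 (adjusted p = 0.0475, up to 0.159 without any single array but GlycoLo replicate 2). The higher Dct goes with melanocytes but is far smaller than the rise of Tyr, 9.68, and against WT it was not called (0.25). Activation of the whole region is also opposed, since the 8 nearest named genes around Tyr had a median of -0.093 (SD 0.25), the furthest being Fah at -0.62. Of these 8, 4 lie above the median of all probe sets in WT hearts. The fall of Fah was called (adjusted p = 0.0149), and Fah also fell in GlycoLo, by 1.21, where Tyr did not rise. A candidate explanation is an additional Tyr copy in the GlycoHi line, as a coat colour marker carried with a transgene would be; Tyr differed by 0.12 between GlycoLo and WT, which this allows. The labels describe no such marker and no sequence was tested, so transcription of the endogenous Tyr gene alone stays open, as does an effect of the GlycoHi genotype on it, which was not tested.

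Myh7 rose in both lines, by 2.75 and 2.89. A return of the fetal gene programme would raise Nppa, Nppb and Acta1 too. Nppa stands at 13.75 in WT, where a further rise would hardly show, so it decides nothing. The median of Nppb and Acta1 was -0.18 in GlycoLo (SD 0.11) and 0.044 in GlycoHi (SD 0.48), and with 2 genes this far apart in GlycoHi the explanation stays open. The 20 genes listed beforehand for hypertrophy and the fetal programme include Myh7 itself. In GlycoLo 1 of them rose, Myh7, and in GlycoHi 2, Myh7 and Gdf15 (4 rose and 2 fell adjusted over the list alone). As Myh7 is the gene to be explained, its own rise does not bear on the explanation. None fell, and camera called the list in neither line (adjusted p = 0.219 and 0.807). Between the lines 3 rose and 1 fell (adjusted p = 0.278). In GlycoHi Myh6 fell by 0.70, but a switch from Myh6 to Myh7 was not tested. Acta1 stood at 0.39 in GlycoHi, and was 0.64 higher there than in GlycoLo (adjusted p = 0.0252, up to 0.0949 without any single GlycoLo array or GlycoHi replicate 1 or 3). Transgenes driven by a cardiac myosin promoter can carry part of the neighbouring Myh7 gene, which may give a probe set signal without a change of the endogenous gene. The lines differed by 0.14, which this allows, but the level of 13.77 and 13.91 lies near the top of the scale, where differences shrink, so the construct and a genotype effect cannot be told apart here. The labels do not name the promoter.

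In GlycoLo, 5 clock genes that peak with Arntl averaged 0.26 against WT and 10 that peak at the other phase -0.49, a difference of 0.75. The 2 groups were drawn up after the changes had been seen, so no p is given, and no clock gene was called against WT. Between the lines 1 of 19 was: Ciart, of the second group, was 1.05 higher in GlycoHi than in GlycoLo (adjusted p = 0.0325, up to 0.136 without WT replicate 1 or 3, GlycoLo replicate 2 or 3 or GlycoHi replicate 1 or 3). Collection of the GlycoLo hearts at another time of day may do this, and so may the genotype. The labels give no time of collection, so the 2 cannot be told apart. Immediate early genes (10 of 20 fell in GlycoHi, 1 in GlycoLo) and heat shock genes (1 of 16 fell in GlycoHi, 0 in GlycoLo) also respond to handling, which the labels do not describe. A difference between the groups in collection or handling was not tested for them and stays open beside the genotype.

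Other splits of the arrays bear on the counts. The 6 arrays of a pair make 10 splits, too few for a share under 0.05, and in each pair 1 split, the real one, gave as many probe sets: 38, 938 and 771, the highest other being 0, 0 and 2. For gene lists the real counts of 16, 26 and 14 were again the highest in 1 split of 10 each, but other splits gave up to 11, 15 and 10 lists. Each of these sets 2 arrays of one genotype and 1 of the other against the reverse, so part of a real difference remains in them. These splits called at most 0, 0 and 2 probe sets, however. Whether a remaining difference accounts for the lists they called was not tested. Of 100 splits of all 9 arrays drawn from 280, 1, the real one, reached 938 probe sets by the F-test. The highest other, at 477, was among the 3 that kept the GlycoHi arrays together, and the remaining 96 reached at most 11. The F-test count was thus reached by a share of splits under 0.05, which argues against an accident of grouping. For the 18 probe sets changed the same way in both lines, the real split was also the only 1 of 100, the highest other being 6. There the group holding WT replicate 1 always served as the control. The choice of control was thus not varied, and an accident of grouping stays open for that count. For probe sets changed in opposite ways the real count was 1 and the highest other 0 (1 split of 100), and a single probe set, already seen, is too few to rest on.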

How the results depend on the processing

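Chosen after the results were seen were the fits of the listed probe sets alone and with the control probe sets. Counts of called probe sets are given for GlycoLo against WT, GlycoHi against WT, GlycoHi against GlycoLo and, where they moved, the F-test, changes in the same direction in both lines and changes in opposite directions. No named gene called in the main fit or in the alternative, and no called list, reversed its sign. Sign changes of genes called in neither were not counted.

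Main values were 38, 938, 771, 938, 18 and 1. Leaving out dim probe sets gave 152, 1679, 1281, 1777, 87 and 2. An offset of 50 gave 134, 1620, 1271, 1641, 91 and 3, and a trended and robust variance 256, 1875, 1547, 2127, 124 and 6. An adjusted p under 0.1 gave 96, 1659, 1274, 1690 and 55. A minimum of 1.5-fold gave 23, 307, 313 and 314. Fitting only the 6 arrays compared gave 15, 502 and 444. The replicate number as a block gave 17 for GlycoLo against WT and 10 for the same direction. Of 369 results of named genes, 33 lost their call with the block and 6 gained one. With only the 6 arrays compared, 59 lost their call and 2 gained one. The 9 pairs with equal numbers correlated at -0.0184 to 0.117 after removal of group means, against -0.113 to 0.0622 for other pairs. Only 3 arrays correlated best with their own number in both other groups, and all were of replicate 1. Their correlations were 0.117 between WT and GlycoLo, 0.102 between WT and GlycoHi and 0.0546 between GlycoLo and GlycoHi. Something shared by the replicate 1 arrays thus stays open, and no array of replicate 2 or 3 showed this pattern.

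The offset, which damps dim probe sets, made 39 of 167 called changes of named genes smaller by more than 1.5-fold, and 37 of these stayed called. Of all 167, 12 lost their call. Among them were Abat and Shmt1 in GlycoLo against WT (adjusted p = 0.0580 and 0.0582), and Cdkn1a and Ppp1r3b in GlycoHi against WT (0.0597 and 0.0563). Ciart lost its call between the lines (0.0822). Against WT in GlycoHi, Asns went from 4.39 to 2.50, Tchhl1 from 2.27 to 0.73, Trib3 from 2.02 to 0.87, Ccnd2 from 1.48 to 0.87 and Sox6 from -1.07 to -0.51. In the same comparison Pfkfb3 went from 0.57 to 0.24, Mcm2 from 0.79 to 0.28 and Psat1 from 0.69 to 0.34. Between the lines Aqp4 went from -1.78 to -0.83, Ddah1 from -1.13 to -0.61 and Shmt1 from 0.95 to 0.39. The sizes of such changes thus depend on the background, which without scanner files was not recomputed.

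The higher share in GlycoLo was 7 of 38, but 54 of 134 with the offset and 49 of 152 without dim probe sets; neither is a scaling of the arrays. Cyclic loess and a common median moved no total by more than 1.5-fold, but with a common median 12 probe sets were higher in GlycoLo. The list counts of 16, 26 and 14 fell to 2, 0 and 0 with an estimated correlation (the 2 being PFK2 isoforms, carried by Pfkfb1, and PPAR alpha targets), to 4 with fry for GlycoLo against WT and to 17 without dim probe sets for GlycoHi against WT. Fry gave 20 lists for GlycoHi against WT and 13 for GlycoHi against GlycoLo. Of the 56 list calls by camera, 34 held with fry and 22 were lost.

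Leaving out single arrays gave 13 to 37 probe sets for GlycoLo against WT, 429 to 769 for GlycoHi against WT, 375 to 651 for GlycoHi against GlycoLo, 483 to 703 by the F-test, 7 to 16 in the same direction and 1 to 1 in opposite directions, and 10 to 17, 18 to 26 and 12 to 17 lists. The lowest list count for GlycoLo, 10, was without GlycoLo replicate 2.

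The arrays whose omission moved a count by more than 1.5-fold were all 9. GlycoLo against WT gave 13, 14 and 14 without WT replicates 1, 2 and 3, and 15, 13 and 15 without GlycoLo replicates 1, 2 and 3. GlycoHi against WT gave 429 and 487 without WT replicates 2 and 3, and 569, 502 and 528 without GlycoHi replicates 1, 2 and 3. GlycoHi against GlycoLo gave 423, 462 and 381 without GlycoLo replicates 1, 2 and 3, and 510, 507 and 375 without GlycoHi replicates 1, 2 and 3.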

Other observations

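The following genes and tests were chosen after the results were seen. Within the stress list, GlycoHi hearts showed rises of some genes known as targets of the transcription factor ATF4, namely Asns, Atf5, Trib3, Gdf15, Chac1 and Ddit3. Of the other targets examined, Sesn2 stood at 0.40 ± 0.09 (adjusted p = 0.0604) and Atf3 at -0.45 ± 0.32 (adjusted p = 0.575). Neither was called, nor was Atf4, the gene of the factor itself, at 0.47 ± 0.12 (adjusted p = 0.0717). Among endoplasmic reticulum chaperones Hspa5 stood at -0.29 ± 0.08 (adjusted p = 0.0983), Hsp90b1 at -0.22 ± 0.08 and Calr at -0.23 ± 0.07, none called. The 9 genes, made up of Atf4 and targets of its factor, averaged 1.43 and the 13 chaperones -0.16, a difference of 1.58. As the groups were chosen from the list in which the rises had been seen, this describes the pattern and tests no explanation; whether an integrated stress response lies behind it stays open.

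Tnnt1, a slow skeletal muscle gene, fell in GlycoHi by 0.86 ± 0.10 against WT (adjusted p = 0.00167), where Myh7 rose. Of 10 slow skeletal muscle genes that do not include Myh7, the other 9 were not called there, and the median of the 10 was -0.05. Several are high in WT hearts, such as Myl2 at 14.32 and Tnnc1 at 13.67, where a rise would hardly show. The median thus does not decide whether other slow muscle genes rose with Myh7.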
